A study of Mus musculus with 7 samples.

How the data were processed

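Total RNA (5 µg per the labels' protocols) from mouse hearts had been labelled with a 3′ one-cycle kit and hybridised to Affymetrix arrays. The deposited table holds 1 intensity per probe set and array, made by the submitters with GCRMA, per the submitters' processing notes; the version is not given in the sources used here. GCRMA corrects the background by probe sequence, normalizes between arrays and summarises the probes of a set. The deposited intensities are linear and were turned into log2 values. Their lowest log2 value was 4.13, so genes that were not expressed lie close to that floor, where differences between arrays are small and folds are understated.

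Probe sets were named through the array platform's annotation, with symbols looked up by gene number in a gene table of assembly GRCm38.p6. Of 45101 probe sets, 34958 had 1 gene symbol, 932 several and 9211 were not listed in the annotation. Those with several or none, and the 64 control probe sets, stayed out. Of the 34945 probe sets left, 34741 matched that table and 204 kept the annotation's symbol. The probe set with the highest mean over all arrays stood for a gene, which left 18193 genes. The planned filter, at least 3 arrays above a log2 value of 4, removed 0 genes because the floor lies above it, so the test over all genes had in effect no filter. A filter at a log2 value of 6, also chosen before the data were examined, left 8201 genes.

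Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with 3 transgenic and 4 littermate arrays and no covariate. Of 44 gene lists fixed before the data were examined, 42 had at least 5 measured genes and were tested with camera at an inter-gene correlation of 0.01, with the correlation estimated from the data and with fry. Of the 1044 genes in the lists, 106 were not analysed here. A direction is given only for lists called in at least 1 of 3 fits: over all genes, above a log2 value of 6, or with the spike-in block and that filter. The skeletal muscle markers, called in none of them, are an exception described in the last part. Single values were compared with exact permutation tests of the absolute difference of means over all 35 splits of the 7 arrays into groups of 3 and 4, two-sided, whose smallest p is 0.0286. Intervals of shares are exact binomial (Clopper-Pearson) at 95%.

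The rule for named genes was fixed before the data were examined. It takes Myh6, Nppa, Nppb, Myh7, Acta1 and Atp2a2 in any case, the 12 largest rises and falls past the threshold with separate groups (filled to 6 per direction by lowest p where fewer pass), and up to 4 passing members of each list, or the 2 members with the smallest p for a called list with fewer than 2. It was applied to the test over all genes and to the spike-in block. The genes named below are only part of those it selected, and not every list called with the spike-in block is described. Mecp2 and Adrb1, which the rule also names, were not analysed here, and unnamed transcripts were skipped.

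The replicate numbers were checked for pairing before the fits were compared. Deviations of same-numbered arrays from their group means correlated at 0.221, 0.605 and 0.479 across genes for replicates 1, 2 and 3, all above 0.1. The numbers were therefore treated as pairing the samples, without any statement in the labels. These values do not establish the pairing. Transgenic replicate 2 correlated more with littermate replicate 4 (0.9945) than with littermate replicate 2 (0.9940). Transgenic replicate 3 correlated more with littermate replicate 1 (0.9949) than with littermate replicate 3 (0.9946), which had another spike-in level. The fit with the replicate number as a block stands beside a result where it changes the call. Littermate replicate 4 has no same-numbered transgenic array and gives no information on genotype in that fit, which rests on 3 pairs. The levels of the poly-A spike-in controls were found when the arrays were inspected. A mean dap value above a log2 value of 10, between 6 and 10, or below 6 defined 3 levels, used as a block after the data were seen. Only the middle and lowest levels hold both genotypes, so in that fit the genotype is estimated from transgenic replicates 1 and 2 against the 4 littermates. The sex-linked profile (mean Xist above or below a log2 value of 7) was a planned covariate.

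Other settings fixed in advance were quantile normalization, median centring, the filter, the mean of a gene's probe sets, every probe set on its own, a variance trend, robust eBayes, array weights, other thresholds, the replicate block, the sex covariate and leaving out each array. The analysis of fold change against gene length was not run because the genome build behind the probe sets is not given in the sources used here. The scripts were tested on simulated data with the real means and spreads. Over all genes 44.8%, 59.7% and 89.4% of genes changed 1.5-, 2- and 4-fold were recovered, with 6 false calls, and with the spike-in block and the log2 6 filter 85.1%, 100% and 100%, also with 6 false calls. The 1 list shifted in the simulation was called and 0 others. These shares test the scripts and do not give the power or the false calls in the real arrays. There Ces1d (13.4-fold, limma adjusted p = 0.107) and Nppa (5.62-fold, limma adjusted p = 0.251) did not pass over all genes. Figures were drawn with matplotlib 3.10.9.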

Results

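Gene expression was measured in hearts of mice aged 2 to 3 weeks with 7 Affymetrix 3′ expression arrays, each carrying 45101 probe sets. The transgenic group (n = 3) carried a Myh6-MeCP2 transgene. MeCP2 is a protein that binds methylated DNA, and Myh6 encodes the main cardiac myosin heavy chain of the adult mouse. The comparison group was wild-type littermates (n = 4). The labels call the samples biological replicates without saying that each came from a separate animal, so the p-values measure the spread between these samples. The deposited GCRMA intensities ran from about 17.5 to between 67217 and 71078 per array, with medians from 25.3 to 26.2, and the number of arrays limits the precision. Values of the introduced gene itself were not analysed here, so no value of that gene checks the labels.

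The arrays differed in ways the genotype does not explain. The dap transcripts, bacterial RNAs added to the sample before labelling, had mean log2 values of 8.60, 8.22 and 8.42 in transgenic replicate 1 and littermate replicates 1 and 3. They lay near the floor in transgenic replicate 2 and littermate replicates 2 and 4, at 4.61, 4.61 and 4.54, and reached 13.15 in transgenic replicate 3. Xist, the RNA that coats the inactive X chromosome, was high (10.39 to 11.35) with Y-linked Eif2s3y low in transgenic replicates 2 and 3 and littermate replicates 1 and 3. The opposite held in transgenic replicate 1 and littermate replicates 2 and 4, where Xist lay between 4.44 and 4.80. Within each spike-in level that held both genotypes, the transgenic array and the littermate arrays thus had opposite sex-linked profiles, in opposite directions at the 2 levels. The first principal component, with 42.7% of the variance, set the arrays near the spike-in floor apart from the others and did not separate the genotypes (exact permutation p = 0.714, two-sided). The second, with 29.1%, separated them (mean score 13.2 ± 7.86 SD in the 3 transgenic arrays, -9.86 ± 2.63 in the 4 littermate arrays, exact permutation p = 0.0286, the smallest that 35 splits allow).

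**Figure D1:**
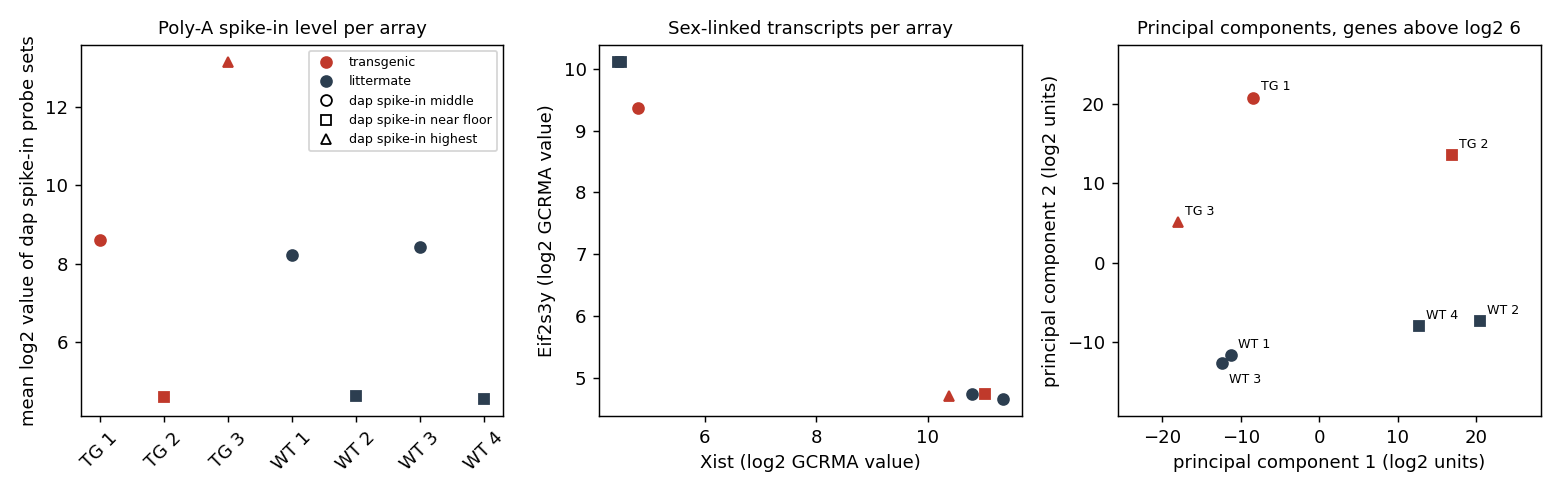
Left, mean log2 value of the dap spike-in probe sets on each array. Middle, log2 GCRMA values of Xist (horizontal) and Eif2s3y (vertical) on each array. Right, scores of the arrays on principal components 1 and 2 of genes above a log2 value of 6. Red symbols are transgenic arrays (TG), dark symbols littermate arrays (WT), and symbol shapes give the spike-in level. All 3 transgenic arrays lie above the 4 littermate arrays on component 2.

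The first comparison asked which genes were expressed differently in MeCP2 transgenic hearts. Ckmt1, which encodes the ubiquitous mitochondrial creatine kinase, rose at least 13.3-fold, from a log2 value of 4.63 ± 0.05 (SD, n = 4) close to the array floor to 8.36 ± 0.37 (SD, n = 3), with a measured log2 fold change of 3.73 (SE 0.17, limma adjusted p = 0.0146). Prkar1b, a regulatory subunit of protein kinase A, rose at least 2.85-fold (measured log2 fold change 1.51, SE 0.08, limma adjusted p = 0.0195). Littermate means of Ckmt1 and Prkar1b (4.78) lay close to the floor, so these folds are minimum values. Both Ckmt1 probe sets were higher, by 3.73 and 2.60, whereas only 1 of the 5 Prkar1b probe sets moved by more than 0.08. These 2 genes were the only calls among 18193 genes in this test, and 1038 genes had an unadjusted p under 0.05 (624 higher, 414 lower). Next in order of p among genes with separate groups, none past the threshold, stood Rhbdl3, Comtd1, Gstt1 and Inhbb on the higher side, with log2 fold changes of 1.28, 0.58, 2.28 and 0.55. Inhbb was close to the floor in littermates (mean 4.38), so its value is a minimum. On the lower side stood Cycs (cytochrome c), Ankrd37, Pgm5, Pdhb (a pyruvate dehydrogenase subunit), Cav1 (caveolin 1) and Tsc22d1, with values from -0.18 for Cycs to -0.39 for Ankrd37. The Myh6 probe set that stood for the gene differed by -0.02 (SE 0.02, limma adjusted p = 0.869), but it was the highest value on each of the 7 arrays (16.04 to 16.12), so it cannot show whether Myh6 changed. The other Myh6 probe set differed by 0.31 (SE 0.32).

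Blocking on the replicate number left 0 calls (lowest limma adjusted p = 0.296, 1659 genes with an unadjusted p under 0.05), with log2 fold changes of 3.72 for Ckmt1 and 1.47 for Prkar1b. That fit rests on 3 pairs and takes nothing on genotype from littermate replicate 4. A lost call may thus come from the smaller fit and not from the pairing. The count also became 0 with the sex-linked profile as a covariate (1099 genes with an unadjusted p under 0.05) or without any single littermate array, and became 15 without transgenic replicate 3, 6 without replicate 2 and 3 without replicate 1.

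When the test was limited to the 8201 genes above a log2 value of 6 on at least 3 arrays, 20 genes rose and 0 fell (limma adjusted p from 0.000223 to 0.0485). Beside Ckmt1 and Prkar1b they included Nppa, the atrial natriuretic peptide gene, expressed in the atria and in stressed ventricles, at 12.88 ± 0.32 (SD, n = 3) against 10.39 ± 0.61 (SD, n = 4), 5.62-fold (limma adjusted p = 0.0401). The detoxifying enzymes Gstt1 (4.85-fold) and Ces1d (13.4-fold), the uridine phosphorylase Upp1 (7.37-fold), Bambi, a decoy receptor of the TGF-beta family (5.80-fold), the prostaglandin D synthase Ptgds (3.94-fold), Timp1, an inhibitor of matrix metalloproteinases (at least 2.85-fold, from 4.95 close to the floor), and Tnnt1, the slow skeletal troponin T (2.35-fold), also rose. The remaining 10 were Rhbdl3, Unc119, Sh2d4a, Smoc2, Bace2, Cyp4b1, Nacad, Comtd1, Tchh and the unnamed transcript 2210407C18Rik, which had the largest measured difference of the 20, 25.5-fold. Those outside the naming rule were named after their values were seen. With the replicate block 16 genes rose and 0 fell, 12 of them shared with the 20. The difference of Nppa was 2.17 among the arrays at the middle spike-in level and 3.02 among those near the floor.

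With the spike-in level as a block, a model chosen after seeing the data, 424 of the same 8201 genes passed, 284 higher and 140 lower in transgenic hearts, and all 20 genes above were among them. The unnamed transcript 2210407C18Rik had the largest measured rise (log2 fold change 4.87, SE 0.10). Among named genes with separate groups the largest measured rise was that of Cd24a, a surface glycoprotein (log2 fold change 4.14, SE 0.53, limma adjusted p = 0.016). Next came Ces1d (4.04), Ckmt1 (3.52 in this fit) and Tnni1, the slow skeletal troponin I that the fetal heart uses (3.33, SE 0.42, limma adjusted p = 0.0152). Upp1 (3.15), Bambi (2.85), the matricellular protein gene Ccn4 (2.78), Nppa (2.59), Sh2d4a (2.53), Gstt1 (2.51), the BMP antagonist gene Vwc2 (2.45) and the sodium channel subunit gene Scn4b (2.40) followed. Ckmt1 and Vwc2 were close to the floor in littermates (means 4.63 and 4.89). Their values in this fit may thus be understated, and their rank among these is not determined. The falls were smaller. Among named genes with separate groups the largest were those of Echdc3 (-1.09, SE 0.21, limma adjusted p = 0.0365), Cavin4, a component of muscle caveolae (-1.08), the oxygen sensor Egln3 (-1.04), the glycogen phosphorylase Pygl (-0.99), Ddah1 (-0.97), Tmc7 (-0.95), Lrrc39 (-0.84), Cmss1 (-0.83), the cyclic nucleotide phosphodiesterases Pde7b (-0.82) and Pde4d (-0.80), Tcea3 (-0.80) and the bicarbonate cotransporter Slc4a4 (-0.78). Cd24a was higher by 5.48 at the middle spike-in level and by 2.79 near the floor, and Egln3 lower, at -1.37 and -0.72.

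Transgenic replicate 3 was alone at its spike-in level and gave no information on genotype in this block. Set against the mean of the 4 littermates, 237 of the 284 higher genes (83.5%) had the same sign in it, against a mean of 66.5% and a maximum of 72.8% in 20 simulations with unchanged genes that shared the littermate arrays. Of the 140 lower genes 97 (69.3%) did, within the simulated values (mean 70.0%, maximum 79.6%), so this array gave no support for the falls. Genes of some lists moved together across arrays, with an estimated correlation of 0.34 for complex I and 0.43 for cell cycle genes. With 1 array such a joint shift cannot be told from genotype, so the share of higher genes does not decide whether they rose. The differences of transgenic replicate 3 were smaller, with medians of 0.33 against 0.66 for the higher genes and -0.12 against -0.60 for the lower. Other scalings moved the split to 314 higher and 251 lower (quantile) and 301 and 290 (median centring). The count was 41, 198 and 399 without transgenic replicates 1, 2 and 3, and 56, 62, 59 and 87 without littermate replicates 1, 2, 3 and 4.

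**Figure D2:**
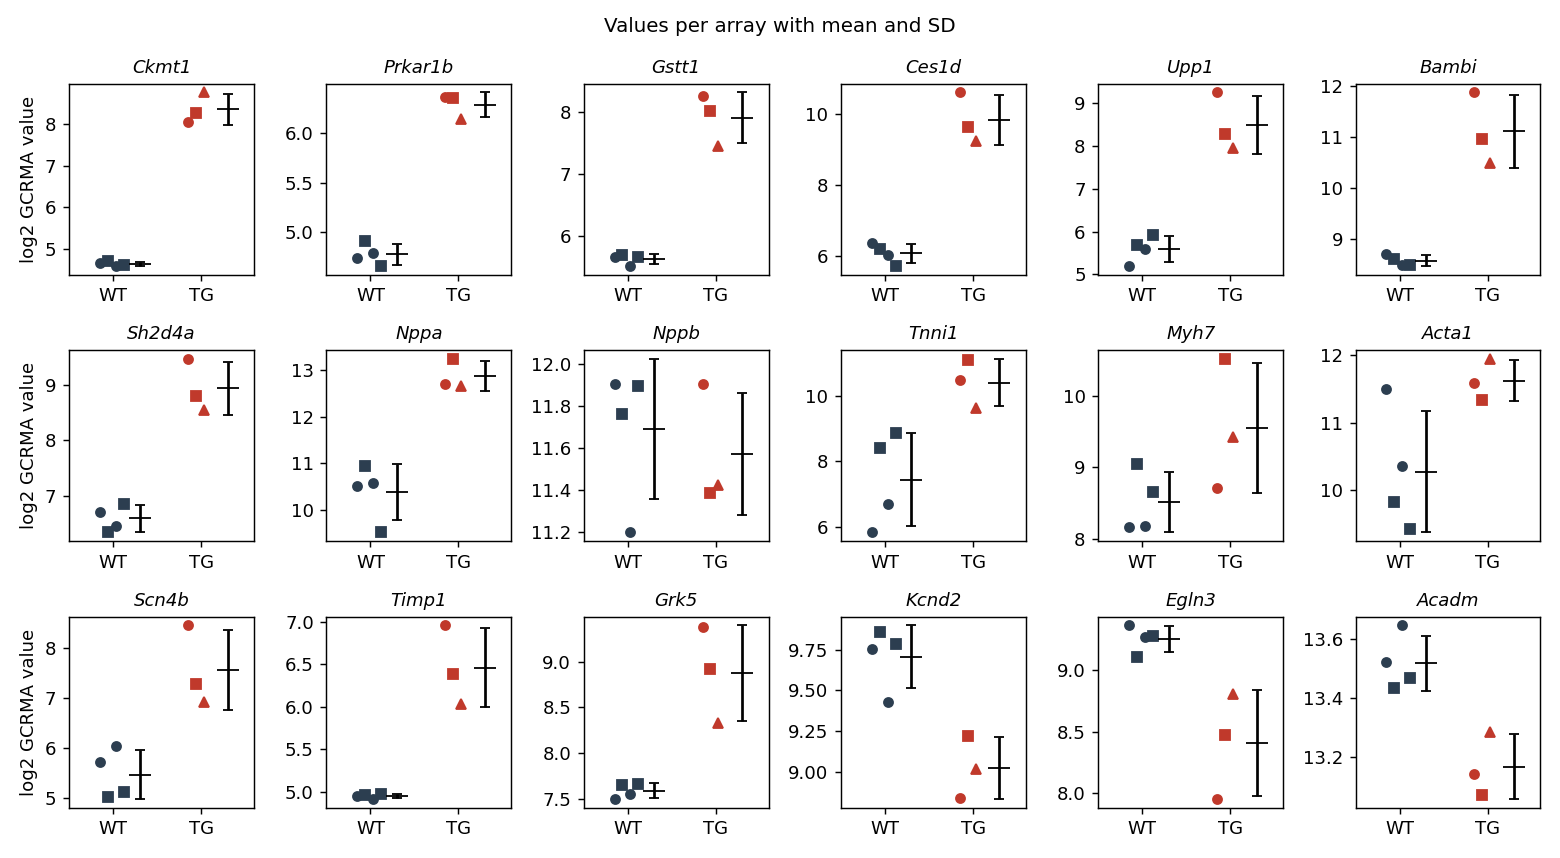
Log2 GCRMA values of 18 genes on each array, for littermate (WT, 4 arrays) and transgenic (TG, 3 arrays) hearts. Circles are arrays at the middle dap spike-in level, squares those near the floor and triangles the array at the highest level, and the bars beside the points give the mean and SD of each group. Nppa, with means of 12.88 and 10.39, has separate groups, and Nppb, with 11.57 and 11.69, has overlapping ones.

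Gene lists fixed before the data were examined described the functional groups. Genes of the respiratory chain stood together on the lower side: 33 of 34 measured genes of complex I (median log2 fold change -0.15, camera adjusted p = 5.05e-18) and 36 of 41 genes of complexes II to V (median -0.13, camera adjusted p = 5.05e-18) were below 0, as were 28 of 37 genes of fatty acid oxidation (median -0.20, camera adjusted p = 4.16e-10). The adjusted p was 0.458 for each of the 3 lists with an estimated correlation. No member passed over all genes, and 2, 2 and 3 members were lower when adjusted over the list alone. Ndufa13 (-0.20) and Ndufb3 (-0.29) of complex I, Cycs (-0.18) and Cox7a2 (-0.13), and the fatty acid oxidation genes Eci2 (-0.20) and Etfb (-0.32) had the smallest p. In the spike-in block, 6 of 37 fatty acid oxidation genes fell, among them Acadm, the medium-chain acyl-CoA dehydrogenase (-0.41), the receptor gene Ppara (-0.44) and Plin5 (-0.62), while Angptl4 rose (1.82); adjusted over the list alone, 15 fell and 3 rose. Ndufa6 (-0.44) was the only 1 of 33 complex I genes to fall there, also when adjusted over the list alone, and 0 of 40 genes of complexes II to V passed either way. The other lists called lower in this mitochondrial group were the mitochondrial ribosome (median -0.07, camera adjusted p = 7.16e-06, adjusted p = 0.458 with an estimated correlation) and the tricarboxylic acid cycle (median -0.04, camera adjusted p = 0.000156, adjusted p = 0.496 with an estimated correlation). The tricarboxylic acid cycle call was lost among genes above a log2 value of 6 (camera adjusted p = 0.112). The list means of these 5 mitochondrial groups overlapped between genotypes (exact permutation p from 0.171 to 0.514). Between same-numbered arrays each of the 5 was lower in the transgenic array in all 3 pairs, as for complex I (-0.21, -0.15 and -0.13), where 3 pairs allow no exact p under 0.25.

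Fibroblast and matrix genes stood on the higher side. Of 15 fibroblast markers 13 were above 0 (median 0.27, camera adjusted p = 0.000278), as were 33 of 42 extracellular matrix genes (median 0.22, camera adjusted p = 0.000295), each with an adjusted p = 0.458 with an estimated correlation. The mean of the fibroblast list was higher by 0.27 (pooled SD 0.07) and that of the matrix list by 0.20 (pooled SD 0.10), and in both every transgenic array lay above every littermate array (exact permutation p = 0.0286, adjusted p = 0.4 over 42 lists). Timp1 was the only member of either list to pass when adjusted over the list alone, in the matrix list, and none passed over all genes. With the spike-in block 5 of 15 fibroblast markers rose, with Lum (0.63), Col1a2 (0.65), Dcn (0.41) and the receptor gene Pdgfra (0.47) among them. So did 10 of 35 matrix genes, with Timp1 (1.72, close to the floor in littermates), Col8a1 (1.04) and Bgn (0.67) among them. Adjusted over the list alone, 9 fibroblast markers rose and 1 fell, and 15 matrix genes rose. Cell cycle genes were above 0 in 39 of 41 cases (median 0.22, camera adjusted p = 1.58e-05, adjusted p = 0.513 with an estimated correlation). The mean of the cell cycle list overlapped between genotypes (exact permutation p = 0.2), with transgenic replicate 3 at -0.002 and littermates from -0.16 to 0.14. Of 20 cell cycle genes measured above log2 6, 8 rose with the spike-in block, 18 when adjusted over the list alone. Rrm2 (1.03), Mcm5 (0.96), Ccna2 (0.73) and Rrm1 (0.71) were among them. Col1a2, Dcn and Pdgfra in transgenic replicate 3 lay 0.11, -0.08 and -0.10 from the littermate mean, and Rrm2 and Rrm1 0.27 and -0.19.

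Markers of other heart cells were tested in the same way. Cardiomyocyte markers (median -0.08, camera adjusted p = 1.22e-06), endothelial markers (median -0.08, camera adjusted p = 0.0023), smooth muscle and pericyte markers (median -0.06, camera adjusted p = 0.00903) and erythroid markers (median -0.11, camera adjusted p = 0.00903) were called lower, with adjusted p = 0.476, 0.496, 0.476 and 0.476 with an estimated correlation. The erythroid call was lost with the replicate block (camera adjusted p = 0.0862). Among genes above a log2 value of 6 the endothelial, smooth muscle and erythroid lists were not called (camera adjusted p = 0.112, 0.0816 and 0.0699). Macrophage markers were above 0 in 15 of 19 cases (median 0.13) and not called over all genes (camera adjusted p = 0.134), but were called higher with the replicate block (camera adjusted p = 0.0227) and among genes above a log2 value of 6 (camera adjusted p = 0.0163, adjusted p = 0.668 with an estimated correlation). The macrophage list mean was 0.03, 0.45 and 0.03 in transgenic replicates 1, 2 and 3. Without transgenic replicate 2 the median was 0.0057 and the camera direction reversed. In the spike-in block 2 of 12 macrophage markers, Ctss (0.91) and Lyz1 (0.62), rose, and 5 when adjusted over the list alone. The exact permutation p over the means of these 5 lists lay between 0.143 for the erythroid and 0.543 for the endothelial list. The sarcomere list was called lower (median -0.02, mean 0.01, camera adjusted p = 0.00106, adjusted p = 0.476 with an estimated correlation), its mean and its test differing in sign. So was the calcium handling list (median -0.08, camera adjusted p = 0.00174, adjusted p = 0.476 with an estimated correlation). The sarcomere and calcium handling calls were lost among genes above a log2 value of 6 (camera adjusted p = 0.161 and 0.403). Both reversed in camera direction under median centring. In the spike-in block the calcium handling genes Asph (-0.74) fell and Casq1, the skeletal muscle calsequestrin (1.02), rose. The list of hypertrophic transcription factors was called lower (camera adjusted p = 0.0379, adjusted p = 0.476 with an estimated correlation) with a median of 0.01. The call was lost with the replicate block (camera adjusted p = 0.0626) and among genes above a log2 value of 6 (camera adjusted p = 0.284). Ppara and Esrrg (-0.64) fell in the spike-in block.

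The stress and fetal gene list was not called over all genes (median 0.23, 12 of 18 above 0, camera adjusted p = 0.0919), although 3 members were higher when adjusted over the list alone, and was called higher among genes above a log2 value of 6 (camera adjusted p = 0.0154, adjusted p = 0.439 with an estimated correlation). With the spike-in block 5 of its 16 members rose, Nppa, Tnni1, Timp1 and Ankrd1 (0.98) among them, and 7 rose and 2 fell when adjusted over the list alone. The atrial list, which also holds Nppa, was not called over all genes (median 0.01, camera adjusted p = 0.619), with 2 members higher when adjusted over the list alone, and was called higher above a log2 value of 6 (camera adjusted p = 0.0209, adjusted p = 0.659 with an estimated correlation). In the spike-in block 2 of its 8 members rose, Nppa and Clu (1.15), and 3 when adjusted over the list alone. Other atrial genes, named after their values were seen, varied widely among littermates and did not pass: Myl7 (0.74, littermate SD 3.02), Myl4 (-1.41, SD 1.77) and Sln (-1.16, SD 1.75). Nppb, the gene of the B-type natriuretic peptide, was at 11.57 ± 0.29 (SD, n = 3) against 11.69 ± 0.33 (SD, n = 4). Myh7 (1.04, SE 0.47), the skeletal actin gene Acta1 (1.34, SE 0.51) and Atp2a2 (-0.09, SE 0.06) did not pass (limma adjusted p = 0.869, 0.856 and 0.869). Of 21 ion channel genes in the spike-in block 3 rose, Scn4b and Kcnk2 (0.88) among them, and 3 fell, the potassium channel gene Kcnd2 (-0.68) and the ankyrin gene Ank2 (-0.58) among them; adjusted over the list alone, 6 rose and 5 fell. Of 21 adrenergic signalling genes Grk5, a kinase of beta-adrenergic receptors (1.55), rose and Pde4d fell. The camera test called neither list (adjusted p = 0.801 and 0.726 over all genes).

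**Figure D3:**
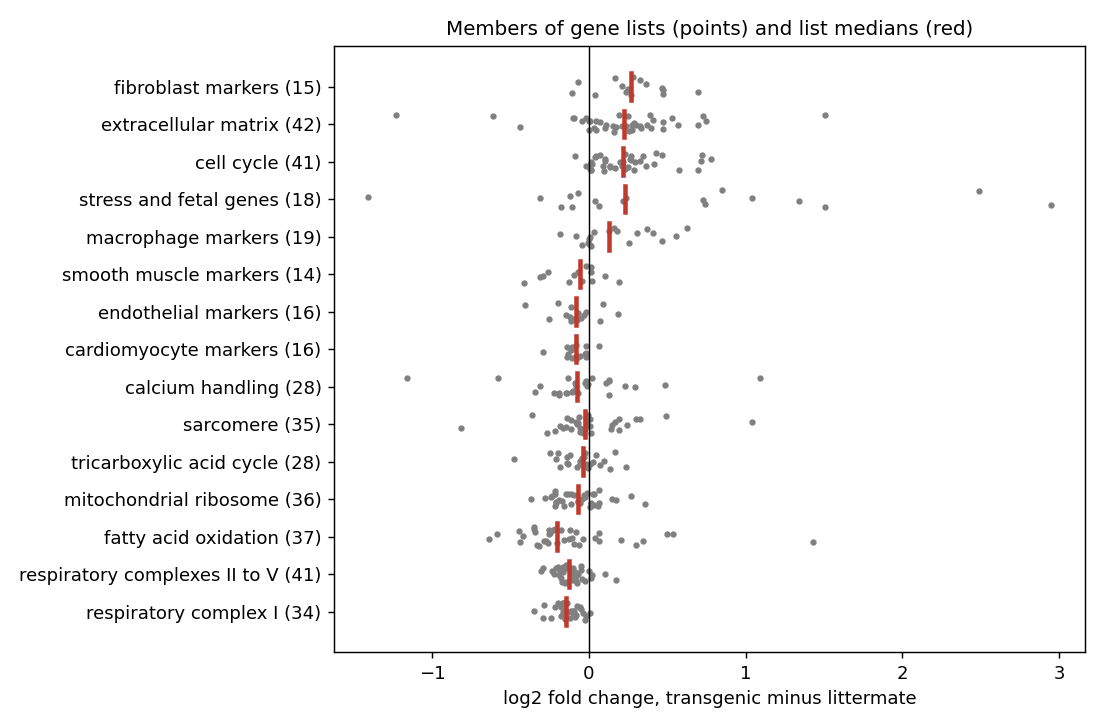
Log2 fold changes (transgenic minus littermate) of the members of 15 gene lists, with the number of measured members in brackets. Each grey point is 1 gene and the red bar is the list median. The median is -0.15 for complex I and 0.27 for fibroblast markers.

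In all, camera with the preset correlation called 15 of 42 lists, 3 higher and 12 lower, and 8 of the 15 also among genes above a log2 value of 6. The calls lost there, all lower, were the sarcomere, calcium handling, tricarboxylic acid cycle, endothelial, smooth muscle, erythroid and hypertrophic transcription factor lists. With an estimated correlation 0 lists were called (3 with an unadjusted p under 0.05), and fry called 0 (6 with an unadjusted p under 0.05). The split depended on scaling: quantile normalization gave 5 higher and 6 lower, and median centring 17 higher and 2 lower. Without transgenic replicate 2 the count was 9. The replicate block changed the call of 5 lists: besides macrophage, erythroid and hypertrophic transcription factor genes, it called immediate early genes higher (camera adjusted p = 0.00229 against 0.0605) and adipocyte markers lower (0.0187 against 0.236, with a median of 0.01 without the block). With an estimated correlation the replicate block called 0 lists (5 with an unadjusted p under 0.05, lowest camera adjusted p = 0.362). Lists of published MeCP2 target genes (median 0.01, camera adjusted p = 0.705) and of imprinted genes (median 0.01, camera adjusted p = 0.909) were not called. The list of MeCP2 corepressor genes was not called over all genes (median 0.07, camera adjusted p = 0.134). It was called higher above a log2 value of 6 (camera adjusted p = 0.0451, adjusted p = 0.659 with an estimated correlation). Of its 22 members 1, Tbl1xr1 (0.92), rose in the spike-in block.

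As a repressor of transcription MeCP2 raises the question of direction. Of the 2 called genes 0 were lower (exact 95% binomial interval of the share lower 0 to 84.2%), and of the 20 genes above a log2 value of 6, 0 were lower (interval 0 to 16.8%). In the spike-in block 33.0% of the 424 were lower (interval 28.6 to 37.7%), a share that was not stable. It was 2.44%, 38.9% and 34.1% without transgenic replicates 1, 2 and 3, and 1.79%, 11.3%, 8.47% and 18.4% without littermate replicates 1, 2, 3 and 4, and became 44.4% with quantile normalization and 49.1% with median centring. Called genes are not independent, so these intervals cover counting only.

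RNA integrity was compared through the 3′ and 5′ control probe sets. The 3′ minus 5′ difference of Gapdh was -0.31 ± 0.05 (SD, n = 3) in transgenic and -0.26 ± 0.08 (SD, n = 4) in littermate arrays, a difference of -0.05, smaller than the pooled SD of 0.07 (exact permutation p = 0.314). Between same-numbered arrays it was -0.02, -0.14 and -0.05, with a mean of -0.07 and an SD of 0.06, where 3 pairs allow no exact p under 0.25. That of beta actin was 1.13 ± 0.09 and 1.21 ± 0.21 (exact permutation p = 0.686), with differences of 0.02, -0.28 and -0.07 between same-numbered arrays.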

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

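The tests of cardiomyocyte share, of RNA integrity between same-numbered arrays and of the spike-in level on the list pattern, and the model with the spike-in block, were chosen after the results were seen. In the 4 littermate arrays, 66 checks for a value far from the rest were made, of which chance gives about 1 in 20. Comtd1 in littermate replicate 2 was 6.09, with the others between 5.97 and 5.99. Gstt1 in littermate replicate 3 was 5.52, with the others between 5.67 and 5.69. The hybridisation controls of littermate replicate 2 had a mean log2 value of 10.94 (others 10.16 to 10.23), and its 5′ probe set of 18S ribosomal RNA stood at 11.68 (others 6.24 to 7.15). In data outside the gene tests, the dap spike-ins of transgenic replicate 3 reached 13.15, above the littermate range of 4.54 to 8.42.

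The first pattern is the number of genes called over all genes. Of the 35 splits of the 7 arrays, 3 gave at least 2 called genes, the real one included, so chance is not excluded by this count. The split of the arrays near the spike-in floor from the rest called 644 genes, many times the real count, which points to a structure of the samples. The split by sex-linked profile called 3. With the log2 6 filter the split of the arrays near the spike-in floor called 1419 genes and the real one 20. That count does not exclude chance either. Among the 8 splits that part all 3 replicate pairs the real one called 2 and the others 0, or 20 and 0 with that filter. RNA integrity stays open: the Gapdh 3′ minus 5′ value differed by -0.048, under the pooled SD of 0.0675, but between same-numbered arrays by -0.07 with an SD of 0.06 over 3 pairs, a pairing that the group comparison leaves out.

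The second pattern is the 424 genes called with the spike-in level as a block. Swapping arrays within the levels gives 9 splits, too few for a share under 0.05: 1 split, the real one, called 424 genes, and the highest of the others called 0. For lists in the same model 1 split, the real one, called as many as 21, and the highest other called 12; with an estimated correlation the real split called 0 of 37 (3 with an unadjusted camera p under 0.05, lowest adjusted p = 0.264). Each level confounds genotype with the sex-linked profile, in opposite directions. With that profile as a further covariate 438 genes were called, 343 of them shared. The covariate left the log2 fold changes as they were (sarcomere median -0.073 with and without it), so the shared count does not weigh the profile as a cause. The genotype effect, the biological explanation the design names, and chance cannot be told apart by these splits.

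The third pattern is the lower mitochondrial and higher fibroblast and matrix lists. By number of lists called, 17 of 35 splits gave at least 15, and the highest other gave 21, so chance is not excluded. The medians of complex I, complexes II to V, fatty acid oxidation, fibroblast and matrix genes kept their pooled sign in 10 of 10 comparisons within levels. They ran from -0.20 and -0.16 for complex I to 0.35 and 0.37 for fibroblast markers. For the arrays compared, this argues against the spike-in level as the cause. The same arrays enter the pooled sign and the lists were chosen after the results were seen, so the count is no independent support. Transgenic replicate 3, alone at its level, is outside these comparisons. Its list means were -0.053 for complex I, 0.0074 for fatty acid oxidation and 0.17 for fibroblast markers. A lower share of cardiomyocytes would raise the markers of other cells alike. The fibroblast list lay above the endothelial one by 0.40 between same-numbered arrays, with an SD of 0.08 over 3 pairs. This goes against the share as the whole cause of the higher fibroblast list only if the replicate numbers pair the samples, which is not established. Between the groups the difference was 0.36 (pooled SD 0.20, exact permutation p = 0.114), which does not decide it. Above the smooth muscle list the fibroblast list lay by 0.59, 0.47 and 0.15 in the pairs (mean 0.40). The SD over the pairs was 0.23, wider than for the endothelial list. Between the groups that difference was 0.365 (pooled SD 0.16, exact permutation p = 0.0571), which does not decide it either. The fibroblast minus macrophage difference was 0.22, -0.02 and -0.005 in the pairs (mean 0.07, SD 0.14). It does not show whether macrophage markers moved with the fibroblast list. For complex I the cardiomyocyte share cannot be told apart from a change within cells. Complex I lay below the sarcomere list by -0.14 (pooled SD 0.04, exact permutation p = 0.0571). Without the sarcomere genes brighter than any of complex I it was -0.17 (pooled SD 0.04, exact permutation p = 0.0286, the smallest possible). The sarcomere genes left include Neb, close to the floor (4.46 in littermates), which can hardly fall, and Myh7, which measured 1.04 higher. The full list holds them too, so neither difference decides about the share. Below the cardiomyocyte markers complex I lay by only -0.054 (pooled SD 0.038, exact permutation p = 0.114), with overlapping groups. A genotype effect stays open as a hypothesis, as does a change in the fibroblasts themselves.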

How the results depend on the processing

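The fits with the spike-in level, with or without sex or filter, the replicate block with the log2 6 filter, and an estimated correlation with a block or that filter were chosen after seeing the data. Against 2 called genes over all genes, there were 20 with the log2 6 filter, 15 with a variance trend, 4 with array weights, 5 at an adjusted p under 0.10, and 0 with the mean of a gene's probe sets (1121 with an unadjusted limma p under 0.05), the replicate block or the sex covariate. The replicate block with the log2 6 filter gave 16, the spike-in block 35, and with the filter 424, or 438 with sex as well. Leaving out 1 array gave 0 to 15 genes. Quantile normalization, median centring, robust eBayes, a 1.5-fold threshold and single probe sets gave 2. For the 424 genes, an adjusted p under 0.10 gave 778 and leaving out 1 array 41 to 399.

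Against 15 lists, an estimated correlation (alone, with the log2 6 filter, with the replicate block, or with the spike-in block and filter) and fry called 0, and leaving out 1 array 9 to 21; the replicate block called 16 and changed the calls of macrophage, erythroid, adipocyte, immediate early and hypertrophic transcription factor lists, and no other list call. Of lists with a direction, sarcomere (median -0.0750), calcium handling (-0.13) and hypertrophic transcription factors (-0.044) reversed in camera direction under median centring, heat shock genes without littermate replicate 2 (medians 0.044 to 0.114 over the arrays left out) and macrophage markers without transgenic replicate 2 (0.0057 to 0.232). The cause was not tested. Myh6 was at 0.15 with the mean of its probe sets and at 0.0033 without transgenic replicate 1 (range -0.034 to 0.0033); its probe set is the highest value on every array, so the small range says nothing about stability. Among other single genes and lists, 994 and 430 comparisons kept their side, 42 and 46 came past the threshold and 16 and 117 lost it. The share of called genes that were lower rests on 2 genes, and its interval of 0 to 84.2% is too wide to show whether it moved. The Gapdh difference (-0.08 to -0.03 without 1 array) moved by less than the pooled SD. Median centring moved the median of all genes from 0.0076 to -0.04. Camera sets a list against all other genes, and only 8201 of 18193 genes passed the log2 6 filter. The direction and camera p of a list over all genes are thus relative to many dim genes.

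Leaving the filter out changed nothing because it removed 0 genes, which tests nothing. The share of lower genes has no value where 0 genes were called. Mecp2 and the gene length analysis were not run. Genes near the log2 floor of 4.13 limit what small folds can show.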

Other observations

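The comparisons in this part were chosen after the results were seen. Of the troponin genes, those of the heart differed little (Tnnt2 -0.02, Tnni3 -0.11, Tnnc1 -0.06, limma adjusted p = 0.869 for each over all genes). Tnnt2 had means of 15.38 in transgenic and 15.40 in littermate hearts, near the highest values of the arrays, where a change may be understated. In the spike-in block the skeletal forms Tnnt1 (1.33), Tnni1 (3.33) and Tnni2 (1.56) rose (limma adjusted p = 0.00357, 0.0152 and 0.0279). The fast skeletal forms Tnnt3 (0.24) and Tnnc2 (0.01) did not pass over all genes and stayed out of that block, with means of 4.71 and 4.37 in transgenic and 4.47 and 4.36 in littermate hearts, close to the floor. Skeletal muscle markers were above 0 in 11 of 13 cases (median 0.01, mean 0.30) and not called (camera adjusted p = 0.0948), although their mean was higher on every transgenic array than on any littermate array (exact permutation p = 0.0571). Of the 4 in the spike-in block Tnni2 rose, and 3 did when adjusted over the list alone, while Myh1, Myh2, Myh4 and Atp2a1 lay close to the floor in both groups. Tnni1 varied with the spike-in level in littermates, at 5.84 and 6.69 on the middle level and 8.39 and 8.86 near the floor, and was 9.63 to 11.07 in transgenic hearts. Of the creatine kinases, Ckmt1 rose while the sarcomeric mitochondrial form Ckmt2 (-0.10), the muscle form Ckm (-0.08) and the brain form Ckb (0.06) did not pass. Of the protein kinase A subunits besides Prkar1b, Prkar1a (0.11), Prkar2a (0.14), Prkar2b (0.13), Prkaca (0.09) and Prkacb (-0.19) did not pass. Ces1d rose from 6.09 to 9.83 with the log2 6 filter, while its relatives Ces1c, Ces1e, Ces1f, Ces1g and Ces1h lay between 4.51 and 4.70 in both groups, close to the floor.

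The score on the second principal component was 20.8, 13.6 and 5.09 in transgenic replicates 1, 2 and 3, against -7.33 to -12.6 in littermates. The unnamed transcript 2210407C18Rik was at 10.26 to 11.55 in transgenic and 5.46 to 6.56 in littermate hearts.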
